A study of Arabidopsis thaliana with 4 samples.

How the data were processed

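Total RNA from at least 6 seedlings per sample was labelled with Cy3 and hybridised to 1 Agilent 44K Arabidopsis array per sample, per the labels' protocols. Plants had grown at 23 °C with 14 h of light and 10 h of dark after 3 days at 4 °C. They stood for 30 min at 25 °C in a 340 cm3 box with 3 µl of solvent or of a 1 M solution of the volatile in it, which would give 8.82 µM if all of it entered the air, beside the nominal 10 µM of the labels.

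The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.10.1.1, while the submitters' processing notes name version 9.1. The processed signal used here is the intensity after the authors' background subtraction within each array, per the file headers, with no scaling between arrays. Flags of the same deposited files, coded 0 or 1, mark spots well above background, saturated spots and outliers. A table of the authors' processed values was also deposited: each of its columns equals the processed signal of the same feature times 1 constant (1.3801 for acetonitrile, 1.4484 for (E)-2-pentenal, 1.3835 for 3-hepten-2-one and 1.9797 for crotonaldehyde). Its values are therefore linear intensity and not centred, with medians of 388.8, 356.7, 352.3 and 280.5. How the authors set the constants is not given in the sources used here.

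Each array had 43803 non-control spots and no saturated spot. The 75th percentile of the processed signal was 1667 for acetonitrile, 1518 for (E)-2-pentenal, 1531 for 3-hepten-2-one and 1048 for crotonaldehyde, so the last array was dimmer. The number of arrays limits the precision. Values were log2 of the processed signal minus each array's 75th percentile. Outlier spots were left out and spots of a probe averaged. A gene took the value of its brightest probe by mean signal, and the 2 brightest probes of a gene differed by over 1 on the log2 scale for 0.9%, 1.3% and 2.6% of 5706 genes after (E)-2-pentenal, 3-hepten-2-one and crotonaldehyde. RefSeq accessions without versions were matched to loci and symbols through a RefSeq gene table of assembly TAIR10.1, used for names only: 34476 of the 43803 spots matched 1 locus, giving 25418 loci. The 18414 genes well above background on all 4 arrays were compared. For a gene not well above background on one side, the brighter level was set against the higher of its own signal and the lowest signal well above background on the dim array, and given as at least N-fold. That lowest signal was 15.8 for acetonitrile, 12.6 for (E)-2-pentenal, 12.8 for 3-hepten-2-one and 10.6 for crotonaldehyde. Some brighter spots were not called well above background, such as BHLH101 at 23.8 in the control, so such bounds are approximate. Folds with 1 side near these signals are imprecise.

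Samples were grouped by their titles. Each volatile was compared with the control and with each other volatile. No test was possible with 1 array per group, so a difference of at least 2-fold was the rule. For 21 gene lists of 355 members the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, a description of these arrays only. The percentile was 100.0 for small heat shock proteins and for chaperones after each volatile, and 39.16, 55.77 and 52.81 for reference genes. The reference gene ACT2 had no matched probe. With members at their bound, the median of the small heat shock proteins was 7.73, 7.30 and 7.73 on the log2 scale after (E)-2-pentenal, 3-hepten-2-one and crotonaldehyde. Bootstrap intervals resampled the members 2000 times. Named genes were, per volatile, the 8 highest and 6 lowest genes, the 3 greatest bounds and up to 4 members of each list past 2-fold. Between volatiles they were the 4 highest and 4 lowest, and over the 3 volatiles the 8 with the highest minimum and the 6 with the lowest maximum. Lists, rules and comparisons were fixed before the data were examined. HSP15.4, AZF3, PRR7, PRR9, CDF1, SEP3 and AP1, outside the rule, were named after their values were seen. So were BTS, BHLH39, BHLH100, BHLH101, FER2, FER3, FER4, RVE2, PRR3 and ELF4-L3.

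Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, cyclic loess, no filter on dim probes, only the genes of mean signal above the median gene, the mean over a gene's probes, the authors' scaled values, and size rules of 1.5-fold and 4-fold. Normexp had been planned on the mean spot signal, a column not found in the scanner files analysed here, so it took the median spot signal, a change made after the data were seen. The settings without the crotonaldehyde array and without the 3-hepten-2-one array were also added then, as was, between volatiles, the use of all genes well above background on the 2 arrays compared. The same was then done against the control. The noise of the simulation had an SD of 0.444 per array. Unchanged arrays against a shared control were simulated 100 times. The steps were tested on simulated arrays of 18414 genes with a noise SD of 0.11, in which 200 genes were changed: 100.0% of those changed by 1.5 and 100.0% of those changed by 3 on the log2 scale were called, and 0 unchanged genes. That noise is the error within an array, far below the 2-fold rule, so this checked the steps only and gives no error rate for the calls. With 0.444 per array, an upper bound for the (E)-2-pentenal and 3-hepten-2-one arrays only, 1710 unchanged genes passed 2-fold in each comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with R 4.3.3 and limma 3.58.1 for normexp, quantile normalization and cyclic loess.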

Results

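Transcript levels were measured in Arabidopsis thaliana seedlings of the Columbia-0 ecotype after 30 min in a closed box with the vapour of a volatile carbonyl compound. The series holds 4 one-colour arrays, 1 for each group: acetonitrile, the solvent and control, (E)-2-pentenal, 3-hepten-2-one and crotonaldehyde, the volatiles at a nominal 10 µM. (E)-2-pentenal and crotonaldehyde are unsaturated aldehydes that differ by 1 carbon in the chain, and 3-hepten-2-one is an unsaturated ketone. RNA came from at least 6 plants per sample. There were no replicates, so no p-value or standard error could be given, and genes were called higher or lower by a fixed size rule of 2-fold. The share of spots well above background was 72.9% for acetonitrile, 73.9% for (E)-2-pentenal, 74.4% for 3-hepten-2-one and 72.6% for crotonaldehyde, and 18414 genes passed on all 4 arrays. Repeat spots of the same probe gave an SD of the log2 difference from control of 0.089 to 0.123 (17 probes), which covers measurement error within an array only. The control, (E)-2-pentenal and 3-hepten-2-one arrays shared 1 slide and scan. The crotonaldehyde array was on another slide scanned at another time, so in each comparison with it slide and treatment cannot be told apart.

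Seedlings exposed to (E)-2-pentenal had far higher transcripts of heat shock proteins than the control. HSP17.8 (AT1G07400) was 340-fold higher, HSP17.6A-CI (AT1G59860) 314-fold, HSP23.5 (AT5G51440) 279-fold and HSP17.6B-CI (AT2G29500) 213-fold, all small chaperones that bind unfolding proteins. HSFA2 (AT2G26150), a heat-induced transcription factor, was 209-fold higher, and HSP101 (AT1G74310), a chaperone that frees aggregated proteins, 99-fold. Among genes well above background on all 4 arrays the greatest difference was that of AT1G71000, at 452-fold, and AT5G54165 was 157-fold higher. AT1G71000 had a control signal of 25.9, near the lowest well above background there. Of the small heat shock proteins, 8 of 9 measured members were higher, with a list median of 49.9-fold. The exception was HSP15.4 (AT4G21870), with a log2 difference of -1.52. A further 8 were not well above background in the control, and among these HSP17.6C (AT1G53540) was at least 4323-fold higher, HSP17.6A (AT5G12030) at least 896-fold and HSP17.6II (AT5G12020) at least 852-fold. The class I small heat shock proteins and the HSP70 genes are close in sequence, and a probe of 1 member can bind transcripts of another. Of 23 chaperones and co-chaperones, 19 were higher and none lower, led after HSP101 by HOP3 (AT4G12400) at 93-fold, BAG6 (AT2G46240) at 71-fold and HSP70B (AT1G16030) at 66-fold. Heat shock factors had 7 of 17 higher, among them HSFA4A, HSFB2A and HSFB2B at 7.0-fold, 6.5-fold and 6.3-fold.

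Many stress-related transcription factors were higher as well after (E)-2-pentenal, to differing extents by family. All 8 zinc finger factors of the ZAT and AZF group were higher, with ZAT11 at 46.4-fold, ZAT6 at 21.4-fold, ZAT12 at 18.6-fold and ZAT7 at 13.7-fold. AZF3 passed only narrowly, at 1.02 on the log2 scale, and its probes disagreed, the other one being at -0.73. Among 12 NAC factors 7 were higher and 2 lower, with ANAC102 at 24.4-fold and ANAC032 at 20.0-fold. DREB2A (AT5G05410), a factor of the drought and heat response, was 48.8-fold higher, and 5 of 7 DREB and CBF factors were higher. Ethylene response factors had 5 of 9 higher, with ERF5 at 27.5-fold, and the early wound, touch and defence genes 13 of 23 higher and 1 lower, with CML37 at 25.4-fold and WRKY33 at 10.3-fold. Detoxification genes formed another group. Glutathione S-transferases, which couple reactive compounds to glutathione, had 10 of 27 higher and 1 lower, led by GSTU7 at 14.0-fold and GSTU24 at 13.2-fold, and 10 of 21 carbonyl and xenobiotic detoxification genes were higher, led by the cytochrome P450 CYP81D11 at 34.3-fold and the glucosyltransferase UGT73B4 at 30.3-fold. Among 19 redox genes 5 were higher, led by the kinase OXI1 at 46.0-fold. The ER folding list had 3 of 14 higher, led by ERDJ3A at 36.2-fold, and the salicylic acid list 5 of 13, led by SARD1 at 8.1-fold.

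Fewer genes were lower after (E)-2-pentenal. PDF1.2 (AT5G44420), a plant defensin, was 59.6-fold lower, its relatives PDF1.2b and PDF1.2c were 33.2-fold and 11.5-fold lower, AT5G57760 was 40.2-fold lower, AT4G16260 14.5-fold and SAUR63 (AT1G29440) 13.3-fold. The defensin genes are close in sequence, and their probes can bind transcripts of each other. PDF1.2b had a signal of 18.0 after (E)-2-pentenal, near the lowest well above background there. Of 9 early auxin response genes 5 were lower, among them IAA6 and IAA3 at 3.0-fold each and IAA2 at 2.7-fold. In the jasmonate list none of 29 was higher and 4 were lower, and in the abscisic acid, drought and cold list 3 of 22 were higher, with CYP707A3 at 4.9-fold. None of 22 photosynthesis genes passed 2-fold. In all, 827 genes were higher and 343 lower, 4.5% and 1.9% of the 18414, and a further 129 genes that were not well above background in the control had a bound of at least 2-fold higher, while 89 that were well above background in the control only had one of at least 2-fold lower. The normexp background correction left 213 lower genes.

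**Figure D1:**
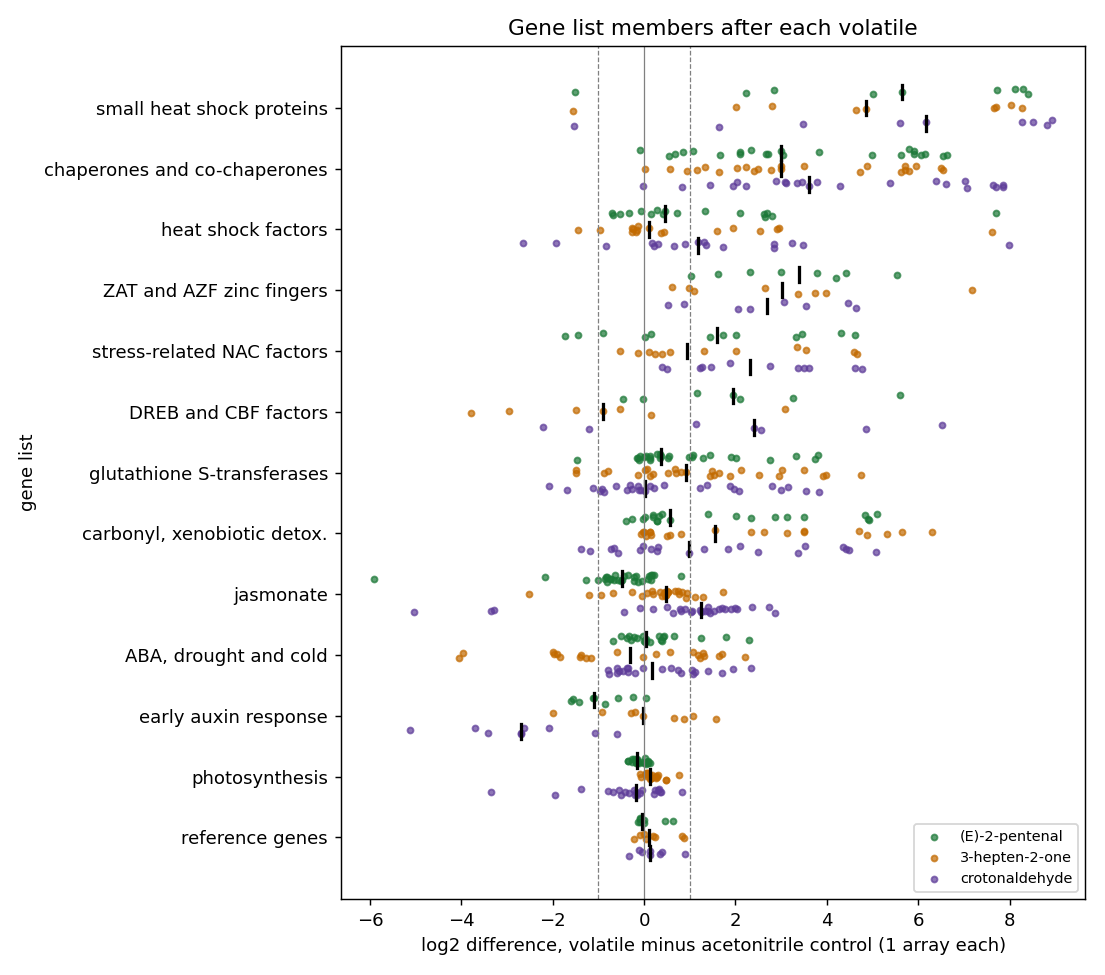
Log2 difference from the acetonitrile control for the measured members of 13 gene lists after each volatile, with 1 point per gene (jittered vertically), black lines at the list medians and dashed lines at 2-fold. Small heat shock proteins and chaperones lie to the right for all 3 volatiles, with medians of 5.64, 4.85 and 6.16 for the former, while reference genes stay within 2-fold.

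After 3-hepten-2-one the same heat shock genes led. HSP17.8 was 311-fold higher than in the control, HSP17.6A-CI 259-fold, HSP17.6B-CI 207-fold, HSP23.5 202-fold and HSFA2 196-fold. ZAT11 was 144-fold higher, AT5G54165 124-fold and HOP3 94-fold. Small heat shock proteins had 8 of 9 higher with a median of 28.9-fold, chaperones 20 of 23 higher with a median of 7.94-fold, and heat shock factors 6 of 17 higher and 1 lower. HSP17.6C, not well above background in the control, was at least 2319-fold higher, HSP17.6A at least 586-fold and HSP17.6II at least 521-fold. The ZAT and AZF group had 6 of 8 higher, the NAC factors 6 of 12, the ethylene response factors 5 of 9 with 1 lower, and the wound, touch and defence genes 13 of 23, with WRKY33 at 12.2-fold. Detoxification genes were higher in 11 of 21 cases, with CYP81D11 at 79-fold, the glucosyltransferase UGT74E2 at 29.3-fold. Glutathione S-transferases had 13 of 27 higher and 2 lower, with GSTU24 at 26.7-fold. Redox genes had 4 of 19 higher, with OXI1 at 72-fold, and the ER folding list 1 of 14 higher and 1 lower, ERDJ3A at 42.6-fold and P58IPK at 2.7-fold lower. Jasmonate genes had 3 of 29 higher and 2 lower, with the synthesis enzymes AOC1 at 3.3-fold and AOS at 2.5-fold.

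The genes lowest after 3-hepten-2-one included several of the daily cycle. ELF4 (AT2G40080), an evening gene of the circadian clock, was 73-fold lower, AT1G07050 55.1-fold, AT5G23240 47.2-fold and the RNA-binding protein GRP7 (AT2G21660) 36.9-fold. AT1G49230 was 31.8-fold lower and COR413IM1 (AT1G29395) 20.4-fold. The clock list had 7 of 13 lower and 1 higher, with LUX 14.2-fold, PRR5 10.6-fold and ELF3 3.7-fold lower and CCA1 2.1-fold higher. The abscisic acid, drought and cold list parted, with 8 of 22 higher, HAI1 at 4.6-fold among them, and 10 lower, including COR15B at 16.4-fold, RD29A at 4.0-fold and RAB18 at 15.6-fold lower. Probes of RAB18 disagreed, with log2 differences from -3.96 to 0.11. Of 7 DREB and CBF factors 3 were lower and 1 higher, DDF2 at 13.8-fold, DDF1 at 7.8-fold and CBF3 at 2.8-fold lower against DREB2A at 8.4-fold higher. The salicylic acid list had 1 of 13 higher, CBP60G at 3.4-fold, and 2 lower, NIMIN1 at 3.1-fold and SARD1 at 2.9-fold. Early auxin genes had 2 of 9 higher, GH3.5 at 3.0-fold and GH3.3 at 2.1-fold, and IAA6 lower at 4.0-fold. Over the 11 well above background on the 2 arrays compared, 2 were higher and 3 lower. No photosynthesis gene passed 2-fold. In all, 1128 genes were higher and 837 lower, so that 57.4% of the genes past 2-fold were higher, against 46.1% (956 higher and 1117 lower) with the authors' scaled values. The normexp background correction left 525 lower genes.

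Crotonaldehyde gave the highest chaperone median and the most lower genes of the 3 volatiles. AT1G71000 was 1255-fold higher than in the control, HSP17.8 485-fold, HSP17.6A-CI 448-fold, HSP17.6B-CI 366-fold, HSP23.5 311-fold, AT5G54165 287-fold, HSFA2 252-fold and HSP70B 232-fold. The AT1G71000 fold rests on a control signal of 25.9, where the lowest well above background was 15.8. HSP17.6C was at least 4789-fold higher, HSP17.4 at least 1204-fold and HSP17.6A at least 1141-fold. Small heat shock proteins had 8 of 9 higher with a median of 71.4-fold (7.73 on the log2 scale with members at their bound, as after (E)-2-pentenal), chaperones 21 of 23 with a median of 12.3-fold, and heat shock factors 9 of 17 higher and 2 lower. ER folding genes had 7 of 14 higher, among them ERDJ3A at 78-fold and the lumenal chaperone BIP1 at 2.5-fold. NAC factors had 10 of 12 higher, ethylene response factors 9 of 9, ZAT and AZF factors 6 of 8, wound, touch and defence genes 14 of 23, and DREB and CBF factors 5 of 7 with 2 lower. DREB2A was 92-fold higher and DREB2C 28.8-fold. Jasmonate genes had 18 of 29 higher, with the repressor JAZ7 at 7.3-fold, and 3 lower, PDF1.2 at 32.6-fold and the storage proteins VSP1 and VSP2 at 10.2-fold and 9.8-fold. Detoxification genes had 10 of 21 higher and 2 lower, with CYP81D11 at 33.5-fold, glutathione S-transferases 10 of 27 higher and 3 lower, with GSTU7 at 14.2-fold, and redox genes 7 of 19 higher and 6 lower, OXI1 at 14.3-fold higher and the ferritin FER1 at 9.5-fold lower. The abscisic acid, drought and cold list had 7 of 22 higher, with COR15A at 5.1-fold, and the salicylic acid list 3 of 13, with PR2 at 4.3-fold.

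The lowest genes after crotonaldehyde were PDF1 (AT2G42840, protodermal factor 1) at 596-fold lower, AT2G33850 at 550-fold, PYK10 (AT3G09260), a glucosidase abundant in roots, at 316-fold, AT4G29030 at 286-fold, SAUR63 at 126-fold and ADS1 (AT1G06080) at 122-fold. Probes of PDF1 ranged from -9.22 to -3.97 on the log2 scale and those of PYK10 from -8.59 to -5.77. Signals on the crotonaldehyde array were 21.3 for PDF1, 24.5 for AT2G33850 and SAUR63, and 25.5 for ADS1. The lowest well above background there was 10.6, so these folds are imprecise. Early auxin genes had 8 of 9 lower, with GH3.3 at 35.0-fold and IAA6 at 12.9-fold, and 3 of 22 photosynthesis genes were lower, LHCB2.1 at 10.2-fold, LHCB3 at 3.8-fold and LHCA4 at 2.6-fold. In the clock list 4 of 13 were lower and 4 higher. LHY was 58.3-fold lower, CCA1 13.4-fold, RVE1 8.0-fold and RVE8 7.3-fold. Among root markers, which had 4 measured members, PYK10 and CASP2 were lower. In all, 1637 genes were higher and 2796 lower, 8.9% and 15.2% of genes, a further 222 had a bound of at least 2-fold higher and 641 one of at least 2-fold lower, and 36 genes were at least 32-fold lower, against 3 after (E)-2-pentenal and 4 after 3-hepten-2-one. Among genes of mean signal above the median gene, 1019 were higher and 810 lower, and without the filter on dim probes 3871 and 3937.

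Genes of the heat shock response also headed the set shared by the 3 volatiles. HSP17.8, HSP17.6A-CI, HSP17.6B-CI, HSP23.5, HSFA2, AT5G54165, HOP3 and HSP101 had the highest minimum of the 3 log2 differences. The lowest maxima belonged to AT5G57760, AT4G16260, SAUR63, AT1G29500, AT1G29450 and PAR1 (AT2G42870). PAR1 was 6.7-fold lower after (E)-2-pentenal, 7.7-fold lower after 3-hepten-2-one and 8.7-fold lower after crotonaldehyde. At least 2-fold higher after all 3 were 409 genes, where independent lists of those sizes would share 4.5, and 92 were lower, where independent lists would share 2.4. All 3 comparisons used the same control array, which alone gives overlap. Unchanged arrays were simulated against 1 shared control, with noise taken from the difference of the (E)-2-pentenal and 3-hepten-2-one arrays. They shared 240 higher and 238 lower genes. The noise is an upper bound for those 2 arrays only. The control and crotonaldehyde arrays did not enter it, so these counts are no upper limit on overlap from the shared control. That noise put 1710 genes past 2-fold in each comparison, more than the 1170 observed after (E)-2-pentenal, so it overstates the noise of that comparison. The 92 lower genes were fewer than in the simulation. How much of the overlap came from the shared control was not measured. Across genes, which are not independent replicates, the log2 differences of (E)-2-pentenal and 3-hepten-2-one correlated at 0.61, those of (E)-2-pentenal and crotonaldehyde at 0.56 and those of 3-hepten-2-one and crotonaldehyde at 0.32 (Pearson). The rank correlations (Spearman) were lower, at 0.38, 0.47 and 0.21. The simulation gave a Pearson correlation of 0.5, which equal noise on every array fixes in advance, so it is no measured baseline. The covariances were 0.300, 0.402 and 0.274, against a simulated 0.197 that follows from the assumed noise.

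**Figure D2:**
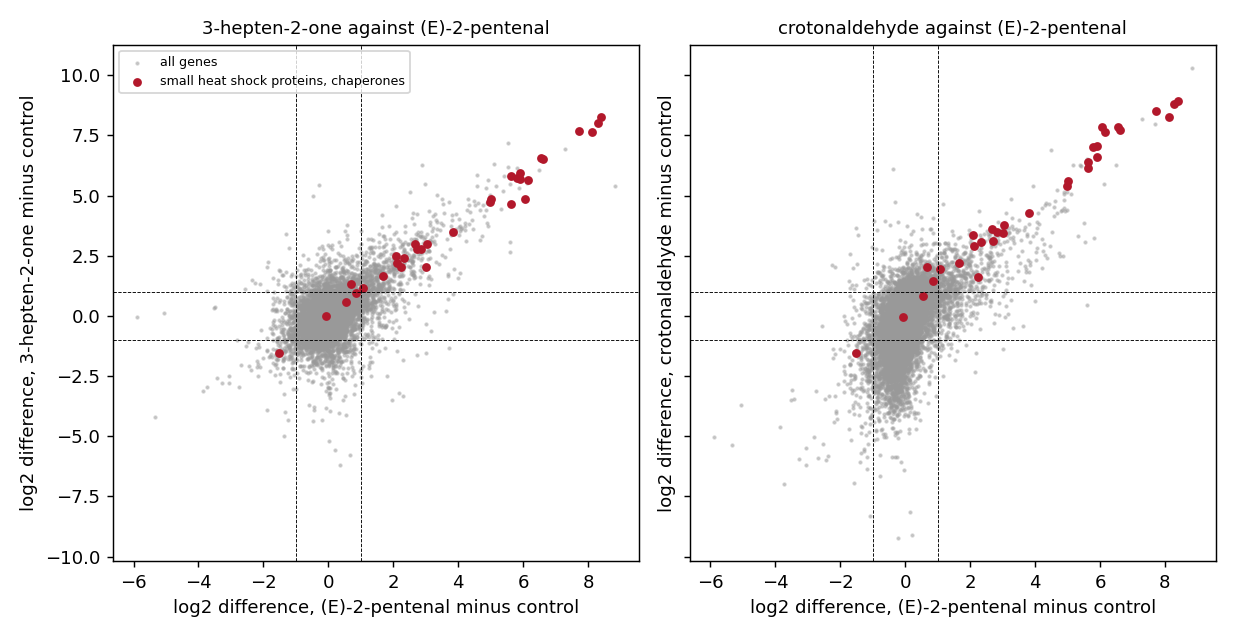
Log2 differences from the control for 18414 genes, with (E)-2-pentenal on both horizontal axes and 3-hepten-2-one (left) or crotonaldehyde (right) on the vertical axis, 1 point per gene, measured small heat shock proteins and chaperones in red, and dashed lines at 2-fold. The red points run along the diagonal in both panels, and the right panel spreads further below 0, with 2796 genes at least 2-fold lower after crotonaldehyde.

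The next comparisons set the volatiles against each other, over genes well above background on all 4 arrays unless stated. Between the aldehydes, 8 of 23 chaperones were at least 2-fold lower after (E)-2-pentenal than after crotonaldehyde and none higher. The chaperone median was -0.76 on the log2 scale (95% bootstrap interval over the 23 genes -1.08 to -0.55, which covers the choice of genes and not replicates), and that of the small heat shock proteins -0.51 (-0.64 to 0.01, 9 genes). Over the 17 small heat shock proteins well above background on the 2 arrays compared, it was -0.16 (-0.52 to 0.06), and none of them passed 2-fold. Jasmonate genes differed more, with a median of -1.45 (-1.75 to -1.17, 29 genes) and 21 at least 2-fold higher after crotonaldehyde, and 7 of 9 early auxin genes were at least 2-fold higher after (E)-2-pentenal, with a median of 1.59 (0.34 to 3.46). Clock genes parted too. Against the control, morning clock genes had medians of -0.39 on the (E)-2-pentenal array and -3.37 on the crotonaldehyde array, and evening ones 0.05 and 1.18. The genes highest after (E)-2-pentenal relative to crotonaldehyde were AT2G33850, PDF1, AT4G29030 and PYK10, with log2 differences of 9.33, 8.98, 8.30 and 7.22. Those lowest were BHLH38 (AT3G56970), a factor of the iron deficiency response, AT2G38240, AT2G14247 and CYP82G1 (AT3G25180), at -6.49, -5.16, -5.03 and -4.90. BHLH38 had a signal of 18.3 after (E)-2-pentenal, near the lowest well above background there. In all, 2505 genes were at least 2-fold higher after (E)-2-pentenal and 1022 lower. Normexp gave 1537 higher genes.

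On the shared slide, 3-hepten-2-one, the ketone, and (E)-2-pentenal, the aldehyde, differed by at least 2-fold in 1 of 23 chaperones, lower after the ketone, and in none of 9 small heat shock proteins. The median difference, ketone minus aldehyde, was 0.02 for chaperones (-0.12 to 0.09). For small heat shock proteins it was -0.17 (-0.46 to -0.04, 9 genes), and -0.51 (-0.71 to -0.17) over the 17 well above background on the 2 arrays compared, of which 2 were at least 2-fold lower. The DREB and CBF median was -2.94 (-3.33 to -2.48), with 7 of 7 measured factors at least 2-fold lower after the ketone, on the array whose evening clock genes were lower than in the control by a median of -1.89. Jasmonate genes had a median of 0.73 (0.55 to 1.02) and early auxin genes 1.13 (0.37 to 1.76). Glutathione S-transferases had a median of 0.39 (-0.02 to 0.68). Genes higher after 3-hepten-2-one were headed by PDF1.2 at 5.86, ELI3-2 (AT4G37990) at 5.72, the ribonuclease RNS1 (AT2G02990) at 5.43 and PDF1.2b at 5.18, and those lower by ELF4 at -6.56, AT1G07050 at -6.46, AT5G23240 at -5.75 and AT1G13470 at -5.63. In all, 713 genes were at least 2-fold higher after 3-hepten-2-one and 773 lower.

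Against crotonaldehyde, 7 of 23 chaperones were at least 2-fold lower after 3-hepten-2-one and none higher, with a median log2 difference of -0.69 (-0.85 to -0.65). Small heat shock proteins had a median of -0.68 (-0.82 to -0.01), or -0.75 (-1.05 to -0.62) over the 17 well above background on the 2 arrays compared, with 5 at least 2-fold lower, DREB and CBF factors -2.93 (-4.69 to -1.57) and jasmonate genes -0.88 (-1.08 to -0.14). Against the control, the evening clock genes had medians of -1.89 on the 3-hepten-2-one array and 1.18 on the crotonaldehyde array. Of the early auxin genes 9 of 9 were at least 2-fold higher after the ketone. PDF1, PYK10, AT2G33850 and AT4G29030 were highest after 3-hepten-2-one relative to crotonaldehyde, at 9.20, 9.12, 9.06 and 8.07, and AT5G23240, ELF4, AT1G07050 and JMJD5 (AT3G20810) lowest, at -8.07, -7.95, -6.73 and -6.09. In all, 2902 genes were at least 2-fold higher after 3-hepten-2-one and 1789 lower.

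Clock genes and tissue markers differed between the arrays beside the groups above. The evening clock genes had a median log2 difference of 0.05 after (E)-2-pentenal (-0.01 with the authors' scaled values), -1.89 after 3-hepten-2-one and 1.18 after crotonaldehyde (7 genes). The morning clock genes, CCA1, LHY, RVE1 and RVE8, had -0.39, 0.73 and -3.37 (4 genes). PRR7, PRR9 and CDF1 of the clock list were in neither group, and PRR7 and CDF1 stayed within 2-fold after crotonaldehyde. None of the 13 members of the clock list well above background on all 4 arrays passed 2-fold after (E)-2-pentenal, while PRR9, dim on the crotonaldehyde array, was at -1.30. Root markers had medians of -0.64, 0.08 and -0.83 (4 genes), the second of which turned to -0.04 with the authors' scaled values and to -0.07 without the filter on dim probes. Of the floral organ markers only SEP3 was measured on all arrays, at -0.26, -0.36 and -0.59. AP1 was at least 7.2-fold lower after 3-hepten-2-one and at least 6.0-fold lower after crotonaldehyde. With it, 2 markers after 3-hepten-2-one and 3 after crotonaldehyde had a bound of at least 2-fold lower, and in each case 1 had a bound of at least 2-fold higher. None of 8 reference genes passed 2-fold in any comparison, with medians of -0.04, 0.11 and 0.13. The last 2 changed sign under other scalings, the lowest value being -0.02. Over all genes the median differences were -0.06, -0.07 and 0.01, and the authors' scaled values moved them to -0.13, -0.19 and -0.14.

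**Figure D3:**
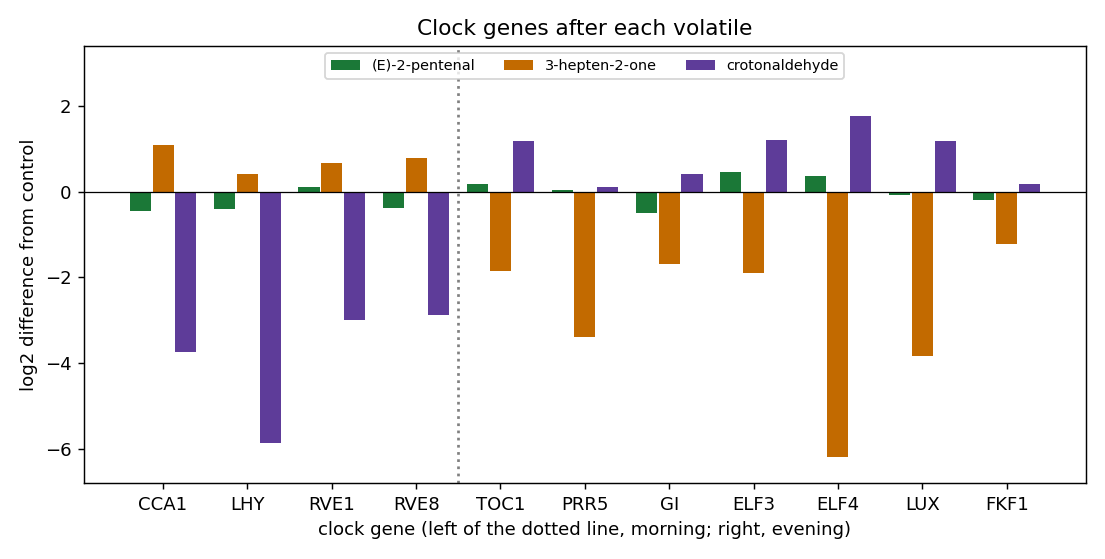
Log2 difference from the acetonitrile control for 11 clock genes after each volatile, with 1 array per bar, morning genes left and evening genes right of the dotted line. PRR7, PRR9 and CDF1 of the clock list are not drawn. After 3-hepten-2-one the evening genes lie below 0, down to -6.19 for ELF4, and after crotonaldehyde the morning genes do, down to -5.87 for LHY.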

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

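No result here was tested, since each group had 1 array, and these items were picked by rules applied after the values were seen.

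The DREB and CBF factors had list medians of opposite sign. The median log2 difference from control was 1.95 after (E)-2-pentenal, -0.89 after 3-hepten-2-one and 2.40 after crotonaldehyde, over 7 measured members. The median was higher by 2.85 after (E)-2-pentenal than after 3-hepten-2-one, arrays that shared a slide, and 3-hepten-2-one minus crotonaldehyde gave -3.30, across slides. These differences between volatiles were not tested. On the same 3-hepten-2-one array the evening clock genes had a median of -1.89, and further morning genes exceeded further evening genes by 2.06. With members at their bound, the 3-hepten-2-one median was -1.46 over 9 members.

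Probes without a matched locus were used in no comparison. Of 3982 such probes well above background on all 4 arrays, 74 were at least 2-fold higher than in the control after all 3 volatiles and 24 lower. The share higher was 1.86%, beside 2.22% of the 18414 genes with a matched locus.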

How the results depend on the processing

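The settings without the crotonaldehyde or the 3-hepten-2-one array, the median spot signal in normexp, and the genes above background on the 2 arrays compared, were chosen after seeing the data, and all others before. No paired analysis was possible because each group has 1 array and no result comes from a test. No count reversed, since counts have no sign, and no list median of at least 2-fold or named difference changed sign. Of 309 named differences, between 302 (normexp) and 309 stayed at least 2-fold in the same direction under 7 of the settings, and 222 of 222 among the genes brighter than the median gene. Dropping the filter and keeping only the brighter genes leave each gene's value as it was. Their 309 of 309 and 222 of 222 were therefore fixed in advance. The sizes of the named differences were less stable: 638 of 2385 values under an alternative moved by more than the SD of repeat spots. The 2385 include the values under those 2 settings, which could not move. Of 471 list medians under an alternative, 461 lay inside the bootstrap interval of the reported value. The correlation of (E)-2-pentenal and crotonaldehyde was 0.46 without the filter, and that of 3-hepten-2-one and crotonaldehyde 0.43 among the brighter genes. Counts of genes past 2-fold, given here as higher then lower where both moved by over 1.5 times, depended on the filter and the size rule by construction. For the remaining moves the cause was not tested. Low signal left at most a bound for 414 genes well above background after (E)-2-pentenal and not in the control, 597 after 3-hepten-2-one and 709 after crotonaldehyde, of which 129, 239 and 222 were at least 2-fold higher. The other way round, 226, 274 and 999 were above background in the control only, of which 89, 126 and 641 were at least 2-fold lower.

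With normexp, 213 genes were lower after (E)-2-pentenal, 525 after 3-hepten-2-one and 61 after all 3, and 1537 were higher after (E)-2-pentenal than after crotonaldehyde. Without the filter, 1247 and 929 passed after (E)-2-pentenal, 1909 and 1406 after 3-hepten-2-one, and 252 were lower after all 3. After crotonaldehyde 3871 were then higher, beside 3937 lower, the latter within 1.5 times of the main count. Between volatiles, 3385 were lower after (E)-2-pentenal than after crotonaldehyde, 1645 higher and 1234 lower after 3-hepten-2-one than after (E)-2-pentenal, and 4022 lower after 3-hepten-2-one than after crotonaldehyde. Among the brighter genes the counts were 478 and 113 after (E)-2-pentenal, 580 and 314 after 3-hepten-2-one, 1019 and 810 after crotonaldehyde, and 27 lower after all 3. The pairs gave 692 and 523 for (E)-2-pentenal against crotonaldehyde, 276 and 318 for 3-hepten-2-one against (E)-2-pentenal, and 922 and 860 for 3-hepten-2-one against crotonaldehyde.

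At 1.5-fold the counts in the same order were 1446 and 1152, 2132 and 2308, and 3476 and 4339 against control, 686 and 350 after all 3, and 4028 and 2941, 1778 and 1933, and 4439 and 3890 for the pairs. At 4-fold they were 310 and 32, 378 and 138, and 408 and 985 against control, 167 and 13 after all 3, and 765 and 129, 130 and 181, and 1116 and 366 for the pairs. Leaving out the crotonaldehyde array, 583 genes were higher and 160 lower after both other volatiles, and leaving out the 3-hepten-2-one array, 553 and 223. The single-volatile counts then stayed within 1.5 times, as did the counts against control and between volatiles over genes above background on the 2 arrays compared.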

Other observations

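Tests on further cycling genes were written before those genes' values were seen. The families in the first paragraph, and the tests on evening clock genes in other volatiles, on brightness, on slides and on the 5 evening genes with PRR3, were chosen after the results were seen.

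Gene families chosen after the values were seen gave further contrasts. Genes whose symbol begins with SAUR, small auxin-induced RNAs, had 6 of 8 measured members at least 2-fold lower after (E)-2-pentenal, 5 after 3-hepten-2-one and 6 after crotonaldehyde, with median log2 differences of -2.01, -1.83 and -4.72, the last of which was -2.83 with normexp. In each case 1 member was at least 2-fold higher, and none of the 8 was brighter than the median gene by mean signal over the 4 arrays. That mean takes in the arrays where members were lower. SAUR63, the lowest member, had a signal of 4887.6 in the control, where the median spot had 281.7. Of the iron deficiency genes 4 of 6 were at least 2-fold higher after crotonaldehyde, with a median of 1.34, BHLH38 by 6.11 on the log2 scale and BTS by 3.09, while the 4 ferritin genes had a median of -1.36, with FER1 at -3.25, FER4 at -2.17, FER2 at -0.56 and FER3 at 0.09. The iron gene medians were -0.03 after (E)-2-pentenal and -0.29 after 3-hepten-2-one, the first of which was 0.01 under cyclic loess. UGT73 glycosyltransferases, some of which are also in the detoxification list, had 6 of 7 measured members at least 2-fold higher after (E)-2-pentenal, 6 after 3-hepten-2-one and 5 after crotonaldehyde, with medians of 4.84, 4.71 and 4.35. With normexp these medians were 3.72, 3.74 and 3.41.

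After 3-hepten-2-one, 7 of 7 evening clock genes were at least 2-fold lower and 1 of 4 grouped morning ones higher. Of the clock list members in neither group, PRR7 and CDF1 stayed within 2-fold, and PRR9 was at least 2-fold higher. A candidate explanation is that these plants were collected at another time of day than the control plants. Among further cycling genes, 11 morning genes had a median log2 difference of 0.45 and 4 measured evening genes -1.61, a gap of 2.06, reached by 6 of 10000 random pairs of lists, though RVE2 (-2.17) and ELF4-L3 (1.33) went against it, and PRR3, dim on this array, was at least 51.5-fold lower. Random lists, here and after crotonaldehyde, were not made of genes that cycle together. Such counts therefore describe these arrays and are no test of collection time. Lower evening genes as a response shared with (E)-2-pentenal were argued against by 1 array, on the control's slide. Its evening clock median was 0.05 (-0.01 with the authors' scaled values), although the 11 further morning genes had a median of -0.64 there, with a gap of -0.42. The evening clock median of 1.18 after crotonaldehyde cannot speak to a shared response. On that array slide and time of day cannot be told apart from crotonaldehyde. The 3-hepten-2-one array shared a slide with the control, and an effect of 3-hepten-2-one itself on the clock stays open and was not tested, though a decrease like that of ELF4 within 30 min would need a transcript half-life of at most 4.8 min even if synthesis had stopped at once.

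After crotonaldehyde the clock pattern ran the other way, with 4 of 4 grouped morning clock genes at least 2-fold lower. Of the clock list members in neither group, PRR7 and CDF1 stayed within 2-fold. PRR9, dim on this array, had a bound of at least 2-fold lower. For plants collected at another time of day the 11 further morning genes were predicted lower and the evening genes higher. The morning median was -2.53, and over the 4 evening genes above background on all 4 arrays the evening median was -0.30, a gap of -2.23 reached by 10 of 10000 random pairs of lists, which met only part of the prediction. PRR3, dim only on the 3-hepten-2-one array, was at 2.00 after crotonaldehyde, and with it the 5 evening genes had a median of 0.54, 3 of them above 0, and a gap of -3.06 reached by 0 of 10000 pairs, as predicted, so the evening direction depends on 1 gene and setting. Time of day, the other slide and crotonaldehyde itself cannot be told apart here, since no control lay on that slide, and the evening genes are few here as after 3-hepten-2-one.

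Crotonaldehyde also had more lower genes than the other volatiles. An average shift with brightness between arrays was argued against as the whole cause. Cyclic loess, which removes such a trend, still gave 2586 genes at least 2-fold lower, beside 772 after 3-hepten-2-one. Of the 2586, 2514 were also lower without it. Genes brighter than the median gene, by a mean that includes the crotonaldehyde array, held 1019 higher and 810 lower. Cyclic loess does not remove a wider spread of dim genes on the dimmer array, so that was not tested. The 36 genes at least 32-fold lower may come from another slide, scan or set of plants, which cannot be told apart from crotonaldehyde because no control was on that slide. PDF1 would need a half-life of at most 3.3 min by its brightest probe, or 7.6 min by the probe with the least difference, if its synthesis had stopped when exposure began, and PDF1.2 after (E)-2-pentenal, on the control's slide, 5.1 min. An effect of crotonaldehyde stays open and was not tested.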
